A study of Mus musculus with 8 samples.

How the data were processed

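Poly(A) RNA of whole aortas from 3 Control and 5 caIKK2EC mice was sequenced from a directional library as single reads of 50 nt on an Illumina HiSeq instrument, per the labels' protocols. Each library comes from 1 mouse of known sex and age, per the labels, so the replicates are separate animals.

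The deposited count table holds raw counts per gene symbol for the 8 libraries, whole numbers with totals of 23461655 to 30808502 per library. The submitters' processing notes name FastQC 0.11.5, STAR 2.7.0e and DESeq2 1.22.2 and the mouse build GRCm38 (mm10). The counting program, the gene annotation and whether counting used the strand are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical gene copies cannot be told apart. The authors' deposited comparison table, whose header calls the Control group WT, gives a log2 fold change with its standard error, a test score (the fold change over its standard error) and p-values for 16671 genes, all of which have a total count of 10 or more. It also holds, as a signal that is never negative, the authors' normalized values per library, which are the deposited counts divided by 1 size factor per library: 100% of these values, multiplied back, came within 0.001 of a whole read count. The deposited regularized log2 values were not used for any test. The table held no columns beyond those of the 8 libraries.

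Of 24411 gene names in the count table, 5938 had a total count of 0, and 27 had been turned into dates. In 23 of these the name was restored from the comparison table by identical counts, and 4 stayed without a name. All 8 columns were matched to the samples by the sample identifier in the column name. Coordinates come from GENCODE release M21 on GRCm38 for 23404 genes, matched by the Ensembl identifier of the comparison table or else by symbol. The 10 most abundant genes took 6.46% to 8.79% of the counts of a library. No pair of libraries differed by as little as sampling noise: the lowest chi-square per degree of freedom was 17.61, between caIKK2EC 4 and 5.

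The sequencing lane was read from the deposited column names. Lane 7 holds the 3 Controls and caIKK2EC 1, and lane 8 holds 4 caIKK2EC libraries, so lane 8 gives no comparison of its own. Within-lane values are therefore the difference of caIKK2EC 1 from the Control mean or the genotype term of a fit with lane as a covariate, in which the lone library is assumed to vary like the others.

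Differences were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3): TMM normalization, the package's default filter on low counts by group (14679 genes kept), a robust quasi-likelihood fit with group as the only term, and Benjamini-Hochberg adjustment with a threshold of 0.05. CPM values are scaled by the TMM factors, and log2 CPM values use a prior count of 2. This design, the rule for named genes, the gene lists and most alternatives were fixed before the data were examined. The gene lists were written from textbook knowledge and cover NF-κB feedback, endothelial state, inflammation, matrix, lipid handling and markers of the cell types that a dissected aorta can hold. Of each list, the report gives how many genes passed over all genes and adjusted over the list alone, and a camera test with a preset correlation of 0.01, adjusted over the 36 lists with at least 3 measured genes. Camera with an estimated correlation and fry were run beside it. In all, 13 list genes, among them T cell receptor and immunoglobulin constant genes, were not found in the count table and are not analysed here. Exact two-sided permutation tests used all 56 splits of the 8 libraries into 3 and 5, on log2 CPM with 0.5 added for single genes, with a smallest possible p of 0.0357.

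The rule named Ikbkb, Bmx and Apoe, then the 10 higher and 10 lower genes with the largest log2 fold change among those past the threshold, with a mean of at least 1 log2 CPM, no overlap between the groups and a symbol that is no clone-style, pseudogene or immune receptor segment name. From each list it named up to 4 members past the threshold with the smallest p, or the 2 members with the highest CPM where none passed. As edgeR called no gene, the same rule was also applied to the DESeq2 calls, a choice made after the result was seen, which left a pool of 674 genes for the part on largest changes. The genes described come from these 2 uses of the rule, with some exceptions. Nqo1, Fdft1, Serpina3n and the inflamed endothelium genes of the closing observations were chosen after values were seen. Xist and Ddx3y, also outside the rule, check the sex labels. Not every gene the rule named is reported here.

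The procedures were tested on simulated data drawn from the real means and library sizes. With 200 genes changed, edgeR recovered 51% of 2-fold and 84% of 4-fold changes among 14554 genes and made 146 calls, of which 11 were false. DESeq2 recovered 69% and 91% among 14679 genes and made 197 calls, of which 37 were false. With no gene changed they made 0 and 11 calls. When the smooth muscle list was shifted by -0.7 on the log2 scale, camera gave it an adjusted p of 1.35e-18, camera with an estimated correlation 0.00213 and fry 0.000527, and camera and fry called 0 of the other lists. Each gene was drawn on its own, so the simulated lists held no correlation between genes. In the real data the estimated correlation was 0.17 for the NF-κB, 0.35 for the macrophage and 0.50 for the smooth muscle list. The list simulation therefore does not test how camera behaves on such lists.

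The settings varied, all named before the data were examined, were size factors of DESeq2, upper quartile scaling, no filter and a stricter filter on low counts (1 CPM in every library of a group), sex, age or a replicate block in the model, leaving out each library, limma-voom, DESeq2 1.42.0 (Wald test, genes with a total count of at least 10), thresholds of 0.01 and 0.1, a test against a 1.5-fold change, and camera and fry as above. Chosen after seeing the data were lane as a covariate, lane 7 alone, leaving out Control 3 and caIKK2EC 2 together, limma-voom with library weights, DESeq2 without Control 3 or without caIKK2EC 2, and edgeR without robust fitting or with bias-adjusted deviances. Scripts ran in R and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.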

Results

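RNA was measured in whole aortas of 8 mice that lack apolipoprotein E and develop atherosclerotic plaques on a Western-type diet, which both groups received for 12 weeks. In 5 mice, called caIKK2EC, tamoxifen (1 mg per 20 g of body weight) had switched on a permanently active form of IKK2, the kinase that activates the transcription factor NF-κB. The Cre recombinase that removes the stop signal in front of this transgene was driven by the arterial endothelial gene Bmx. The 3 Control mice were littermates with the silent transgene and no Cre, and they received tamoxifen as well. The series describes activation at early or at late disease, and which of these applies to the 8 mice is not given in the sources used here. All mice were 18 or 19 weeks old, and all were female except Control 3. A fit with sex as a covariate therefore compares the groups among females only and is nearly the same test as leaving out Control 3. Control 3 was also the only Control of 19 weeks, an age it shared with caIKK2EC 2, 4 and 5. Among Controls, age can therefore not be told apart from Control 3. Total counts were 25952882, 26603624 and 23587995 in Control 1 to 3 and 24844125, 23461655, 24325695, 27883899 and 30808502 in caIKK2EC 1 to 5. According to the deposited column names, the 3 Controls and caIKK2EC 1 were sequenced in lane 7 and caIKK2EC 2 to 5 in lane 8. Lane 8 thus holds caIKK2EC libraries alone, and the only within-lane comparison sets 1 caIKK2EC library against 3 Controls.

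Ikbkb, the gene for IKK2 (chromosome 8, 22659212 to 22706589, minus strand, GRCm38), was at 98.4 ± 4.07 CPM (read counts scaled to a common library size; SD, n = 5) in caIKK2EC aortas and at 79.7 ± 12.4 CPM (SD, n = 3) in Control aortas. All 5 caIKK2EC libraries lay above all 3 Controls (exact two-sided permutation p = 0.0357, the smallest that 3 against 5 allows). The quasi-likelihood test of edgeR over all genes did not call the log2 fold change of 0.30 (SE 0.12, Benjamini-Hochberg adjusted p = 0.237). The log2 difference was 0.18 without Control 3 and 0.32 within lane 7. Whether reads of the transgene were assigned to this gene is not given in the sources used here. Bmx (chromosome X, 164192842 to 164258193, minus strand), whose regulatory sequence drives the Cre, had a log2 fold change of 0.55 (SE 0.28, edgeR adjusted p = 0.342, exact permutation p = 0.179), and 0.26 without Control 3. Apoe (chromosome 7, 19696109 to 19699188, minus strand), the gene disrupted in all 8 mice, still gave 32.4 ± 13.4 CPM (SD, n = 3) in Control and 49.9 ± 6.69 CPM (SD, n = 5) in caIKK2EC libraries, with an edgeR adjusted p of 0.267 and an exact permutation p of 0.107. Its log2 fold change was 0.62, and 0.31 without Control 3. The sex labels matched the counts in all 8 libraries. Xist, which is transcribed from the inactive X chromosome, had 22 counts in Control 3 and 4961 to 10021 in the others. The Y-linked gene Ddx3y had 2721 counts in Control 3 and 4 to 7 in the others.

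The comparison of caIKK2EC with Control asks how continuous NF-κB signalling in arterial endothelium alters the transcriptome of the atherosclerotic aorta. NF-κB pathway genes, chemokines, macrophage markers and antigen presentation genes were at higher levels in caIKK2EC aortas, and contractile smooth muscle genes were at lower levels. Averaged over the genes of each list, the log2 fold change was 0.53 for NF-κB members and feedback genes, 0.63 for chemokines, 0.77 for macrophage markers, 0.72 for genes of major histocompatibility complex (MHC) class II and -0.67 for contractile smooth muscle genes. Of 36 lists fixed before the data were examined, camera with a preset correlation of 0.01 between genes called 21 higher and 4 lower. With an estimated correlation it called 0 lists (lowest adjusted p = 0.188). Fry, which asks whether a list's genes move one way without comparing them with other genes, called 8 higher and 0 lower. Those 8 were the NF-κB, endothelial activation, chemokine, cytokine, macrophage, dendritic cell, MHC class II and oxidative stress lists. All other lists that camera called were not called by fry. An exact permutation test on the mean level of each list called no list after adjustment over the lists (lowest adjusted p = 0.0918). Its unadjusted p cannot fall under 0.0357, a floor reached by the 8 lists that fry called, the smooth muscle list and some others. The unadjusted exact p was 0.0714 for the interferon and foam cell lists, 0.143 for proliferation, 0.214 for complement and 0.25 for T cells. No single gene passed edgeR's quasi-likelihood test at an adjusted p of 0.05 among 14679 tested (lowest adjusted p = 0.107). Below, counts of genes that passed are those of edgeR unless DESeq2 is named. At an unadjusted p under 0.05, 1418 genes were higher and 1097 lower, 17.1% of those tested where 5% would fall by chance on average. Single chance groupings can lie far from that average: other splits of the 8 libraries into 3 and 5 gave up to 2285 such genes, against 2515 here. DESeq2 called 652 genes higher and 217 lower, the same genes as in the authors' deposited table. On simulated counts with 200 genes changed, 18.8% of the DESeq2 calls were false (37 of 197) and 7.5% of the edgeR calls (11 of 146). Each simulated gene was drawn on its own, so these shares need not hold for the real calls. Other splits of the real libraries, which mix the genotypes, gave up to 517 DESeq2 calls. In 1029 genes every caIKK2EC library lay above every Control and in 473 below, together 10.23% of genes where chance gives 3.57% on average. Among the genes given below as called or passing, the groups overlapped for Lcn2, Cx3cl1, Osm, Il7r, Cd4, Mki67, Acta2, Myh11, Tagln, Nqo1 and Fdft1. The count changed with the model and with single libraries. With age as a covariate edgeR called 407 genes higher and 254 lower, but among Controls that term sets only Control 3 apart. Without caIKK2EC 2 edgeR called 230 higher and 129 lower, while DESeq2 called 356 higher and 33 lower without Control 3, the male. No gene passed in edgeR with lane as a covariate.

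**Figure D1:**
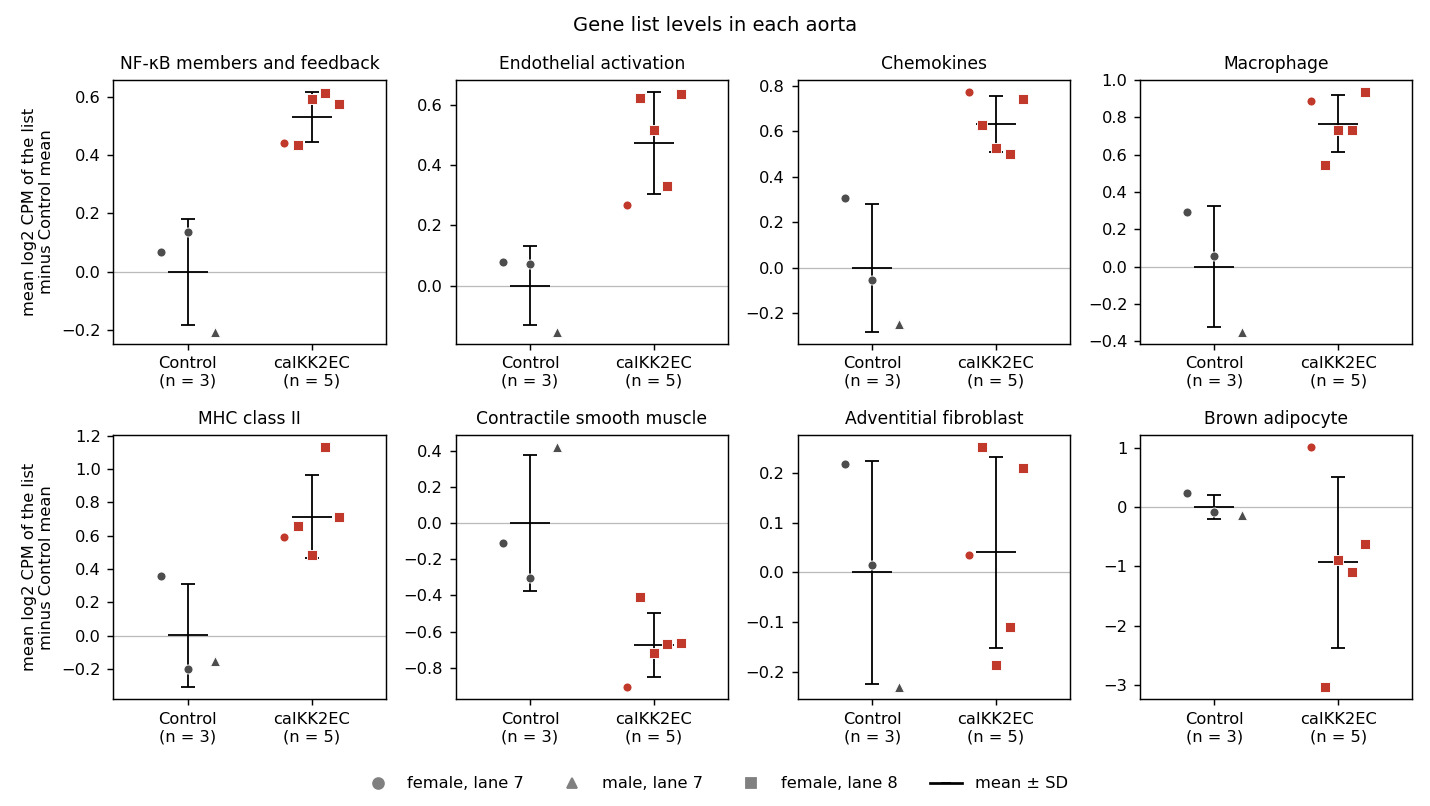
Mean log2 CPM of 8 gene lists in each library, with the Control mean set to 0 (vertical axis), for the 3 Control and 5 caIKK2EC libraries, where circles are females and the triangle the male in lane 7, squares are females in lane 8, and bars give the mean ± SD. All 5 caIKK2EC libraries lay above all 3 Controls for the NF-κB, endothelial activation, chemokine, macrophage and MHC class II lists and below them for the smooth muscle list, while brown adipocyte markers ranged from -3.03 to 1.00 within caIKK2EC.

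Genes of the NF-κB pathway and its feedback loop were higher in caIKK2EC aortas. Of 19 measured, 13 rose and 0 fell when adjusted over the list alone, 6 did not pass, and 0 passed over all genes. Birc3, which encodes an inhibitor of apoptosis and is a well-known NF-κB target (chromosome 9, 7848699 to 7873186, minus strand), rose 1.94-fold from 21.1 ± 3.24 CPM (SD, n = 3) to 41.0 ± 4.38 CPM (SD, n = 5). Nfkbie, an inhibitor of NF-κB (chromosome 17, 45555703 to 45563169, plus strand), rose 2.05-fold from 12.0 ± 1.62 to 24.6 ± 3.98 CPM. Tnfaip3, which encodes the feedback inhibitor A20 (chromosome 10, 19000910 to 19015657, minus strand), rose 1.94-fold from 38.9 ± 8.90 to 75.6 ± 11.6 CPM. Bcl3 rose 1.52-fold and Nfkbia, which encodes IκBα, 1.36-fold. Tnfaip2, the most abundant member, was at 178 ± 67.7 CPM in Control and 259 ± 30.8 CPM in caIKK2EC without passing, and its log2 fold change of 0.54 was 0.27 without Control 3. The list had a camera adjusted p of 2.40e-08, adjusted p = 0.188 with an estimated correlation, and a fry adjusted p of 0.0200. Within lane 7 its mean difference was 0.44, with Birc3 at 0.94, Nfkbie at 0.87 and Tnfaip3 at 0.57 on the log2 scale.

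Adhesion molecules and other genes of activated endothelium were partly higher, and the call on markers of endothelial identity depended on the setting. Of 15 activation genes, 6 rose and 0 fell when adjusted over the list alone, against 0 over all genes. Sele, which encodes E-selectin, the adhesion molecule made by inflamed endothelium (chromosome 1, 164048234 to 164057677, plus strand), rose 1.91-fold from 23.5 ± 3.98 to 44.8 ± 10.5 CPM (SD, n = 3 and 5). The monocyte chemokine gene Ccl2 rose 1.94-fold, Lcn2, encoding the iron-binding protein lipocalin 2, 2.36-fold, and the membrane-bound chemokine gene Cx3cl1 1.61-fold. The log2 fold change of Lcn2 was 1.24, from 0.99 without Control 2 to 1.84 without Control 3, and Control 3 (106 CPM) lay above caIKK2EC 3 (95.4 CPM). Within lane 7 the log2 difference of Sele was 0.49 against 0.93 over all libraries, and that of Cx3cl1 0.02 against 0.68. Vcam1, the gene of another leukocyte adhesion molecule, was at 495 ± 89.5 CPM in Control and 725 ± 191 CPM in caIKK2EC and did not pass (edgeR adjusted p = 0.271). Its log2 difference was 0.55 over all libraries and -0.06 within lane 7. Selp was at 151 ± 45.1 and 190 ± 38.2 CPM and did not pass either, and its log2 fold change of 0.33 was 0.12 without Control 3. The activation list had a mean log2 fold change of 0.47 and a camera adjusted p of 6.58e-05, adjusted p = 0.188 with an estimated correlation, and a fry adjusted p of 0.0251. Within lane 7 the mean was 0.27, with a camera adjusted p of 0.125 when lane was a covariate. Endothelial identity markers averaged 0.21 over 18 genes, of which 0 passed in edgeR adjusted over the list alone (camera adjusted p = 0.0710), and -0.04 without Control 3. DESeq2 called 1 of them over all genes, Vwf, the von Willebrand factor gene (1.51-fold, DESeq2 adjusted p = 0.0488). Its log2 fold change of 0.59 was 0.41 without Control 3, and DESeq2 on females alone did not call it (adjusted p = 0.227). The list was called higher with age as a covariate (0.32, adjusted p = 0.00346), without Control 1 (adjusted p = 0.0477), Control 2 (0.39, adjusted p = 0.00313), caIKK2EC 2 (adjusted p = 0.0402) or caIKK2EC 5 (adjusted p = 0.0320), and with lane as a covariate (0.32, adjusted p = 0.0425). Genes of flow response and endothelial quiescence averaged 0.25 with 0 of 18 passing. Their camera adjusted p was 0.0241, adjusted p = 0.485 with an estimated correlation, and without Control 3 the mean was 0.06 (adjusted p = 0.589). That call was also lost without caIKK2EC 3 (adjusted p = 0.0537) and with lane (0.12, adjusted p = 0.616) or sex (0.06, adjusted p = 0.605) as a covariate.

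Chemokine and cytokine transcripts were higher in caIKK2EC aortas. Of 26 chemokines, 10 rose and 0 fell when adjusted over the list alone and 0 passed over all genes, while DESeq2 called 9 of them over all genes. Cxcl16 rose 1.77-fold from 152 ± 40.2 to 269 ± 26.0 CPM (SD, n = 3 and 5), the monocyte chemokine gene Ccl12 2.01-fold, and Cxcl5, which encodes a neutrophil attractant, 2.41-fold. The most abundant member, Cxcl12, had a log2 fold change of 0.30 (SE 0.16) and did not pass, with 0.48 without Control 1 and 0.19 without Control 2. The chemokine list had a camera adjusted p of 2.06e-07, adjusted p = 0.188 with an estimated correlation, and its mean was 0.77 within lane 7. Cytokines averaged 0.71 over 22 genes, of which 10 were higher at an unadjusted p under 0.05 and 0 passed adjusted over the list alone. DESeq2 called 3 of these 22 over all genes, among them the inflammatory cytokine gene Osm, with a log2 fold change of 0.89 over all libraries and 0.35 within lane 7. The cytokine list had a camera adjusted p of 1.24e-06, adjusted p = 0.188 with an estimated correlation, a mean of 0.61 within lane 7 and 0.48 without Control 3. Fry called both lists, with adjusted p-values of 0.0249 for chemokines and 0.0209 for cytokines.

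Macrophage markers were higher by 0.77 on the log2 scale on average. Of these, 16 of 21 rose and 0 fell when adjusted over the list alone, with 0 passing over all genes in edgeR and 13 in DESeq2. Cd68, a lysosomal protein of macrophages (chromosome 11, 69664213 to 69666153, minus strand), rose 1.76-fold from 395 ± 85.7 to 694 ± 33.1 CPM (SD, n = 3 and 5). Adgre1, which encodes F4/80, rose 1.93-fold, the Fc receptor gene Fcgr1 1.88-fold and the complement gene C1qb 1.88-fold, whose log2 fold change of 0.91 was 0.58 without Control 3. The list had a camera adjusted p of 5.62e-14, adjusted p = 0.188 with an estimated correlation, and a fry adjusted p of 0.0200. Its mean was 0.89 within lane 7. Genes of lipid-laden foam cells averaged 0.57, and 9 of 15 rose and 0 fell when adjusted over the list alone (0 over all genes). Spp1, which encodes osteopontin (chromosome 5, 104435118 to 104441050, plus strand), rose 2.05-fold from 3645 ± 1112 to 7490 ± 1432 CPM, and Lgals3, the galectin-3 gene, 1.55-fold. The foam cell list had a camera adjusted p of 2.43e-06, adjusted p = 0.328 with an estimated correlation, and its mean was 0.78 within lane 7 and 0.33 without Control 3.

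Antigen presentation genes were higher as well. Of 10 MHC class II genes, 8 rose and 0 fell when adjusted over the list alone (0 over all genes). Cd74, the invariant chain, rose 1.80-fold, H2-Ab1 1.69-fold and H2-Aa 1.57-fold. The MHC class II list averaged 0.72, with a camera adjusted p of 1.09e-06, adjusted p = 0.200 with an estimated correlation, and its mean was 0.59 within lane 7. Of 14 dendritic cell markers, 4 rose and 0 fell when adjusted over the list alone (0 over all genes), among them Irf8, a transcription factor of dendritic cells and macrophages, at 1.84-fold and the integrin gene Itgax, which encodes CD11c, at 1.67-fold. The dendritic cell list averaged 0.56 and also 0.59 within lane 7, with a camera adjusted p of 6.58e-05 and adjusted p = 0.200 with an estimated correlation. Genes of MHC class I averaged 0.37 over 11 genes and 0.45 within lane 7, and of these Nlrc5, which encodes their transactivator, was the 1 gene that rose in edgeR when adjusted over the list alone (0 over all genes). DESeq2 called 2 of the 11 over all genes, Nlrc5 and B2m. The class I list had a camera adjusted p of 4.57e-05, adjusted p = 0.328 with an estimated correlation, and its mean was 0.21 without Control 3. Interferon response genes averaged 0.40 over 21 genes, and 0 passed adjusted over the list alone. Their camera adjusted p was 2.03e-05, adjusted p = 0.416 with an estimated correlation, and their mean was 0.68 within lane 7 and 0.15 without Control 3.

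Lymphocyte markers moved less evenly. The T cell list averaged 0.50 with 0 of 15 passing adjusted over the list alone, and DESeq2 called 2 of them over all genes, Il7r (1.73-fold) and Cd4 (1.95-fold, a log2 fold change of 0.96 that was 0.42 within lane 7 and 0.64 without Control 3). Its camera adjusted p was 0.00695, adjusted p = 0.417 with an estimated correlation. Without Control 3 the mean was 0.08 (adjusted p = 0.369), with sex as a covariate it was also 0.08 (adjusted p = 0.379), without Control 1 it was 0.84, and with lane as a covariate it was 0.34 (adjusted p = 0.125). B cell markers averaged -0.13 over 15 genes (camera adjusted p = 0.880), 0.38 with a stricter filter on low counts, 0.27 without Control 2 and -0.62 without Control 3, where camera called the list lower (adjusted p = 0.0440). When adjusted over the list alone 1 rose and 1 fell, Cd22 at 1.71-fold and the transcription factor gene Ebf1, which adipose and stromal cells express too, at 0.718-fold. Plasma cell genes averaged 0.70 with 0 of 6 passing and a camera adjusted p of 0.0241, adjusted p = 0.200 with an estimated correlation. The call was lost without Control 1 (adjusted p = 0.116), without caIKK2EC 4 (adjusted p = 0.0575), without a filter on low counts (0.44, adjusted p = 0.0874), and with age (adjusted p = 0.0757) or lane (adjusted p = 0.266) as a covariate. In that list caIKK2EC 1 lay 0.39 above the Control mean. Neutrophil markers averaged 0.02 (camera adjusted p = 0.354), 0.43 with a stricter filter on low counts, where camera called the list higher (adjusted p = 0.0459), and -0.23 without Control 3. Of its 9 genes, 2 rose when adjusted over the list alone, Csf3r, the receptor gene for granulocyte colony-stimulating factor, at 1.90-fold and Mmp8 at 1.80-fold. Mast cell markers (mean 0.11, and -0.03 without Control 3, 0 of 7 passing) had a camera adjusted p of 0.878. Genes of lymphoid stroma (mean 0.32, and -0.14 without Control 3, 1 of 12 rising, Ccr7) had an adjusted p of 0.129, and 0.0390 without caIKK2EC 3. Thymocyte genes averaged -0.82 with 0 of 9 passing (camera adjusted p = 0.0294, adjusted p = 0.418 with an estimated correlation). The mean was -0.39 without Control 1 (adjusted p = 0.213), and the call was also lost without caIKK2EC 1 (adjusted p = 0.0652) or caIKK2EC 3 (adjusted p = 0.0537) and with a stricter filter on low counts (adjusted p = 0.0566). With lane as a covariate the mean was -1.77 (adjusted p = 0.00394).

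Contractile genes of vascular smooth muscle, the main cell type of the aortic wall, were lower in caIKK2EC aortas. Of 18 measured, 14 fell and 0 rose when adjusted over the list alone, 0 passed over all genes in edgeR and DESeq2 called 4 lower. Myh11, the smooth muscle myosin heavy chain (chromosome 16, 14194535 to 14291372, minus strand), was at 5199 ± 2678 CPM (SD, n = 3) in Control and at 2561 ± 710 CPM (SD, n = 5) in caIKK2EC, with a log2 fold change of -1.02 (SE 0.32). Acta2, smooth muscle α-actin (chromosome 19, 34241090 to 34255590, minus strand), was at 11942 ± 4354 and 6809 ± 1941 CPM, with a log2 fold change of -0.81 (SE 0.28). Tagln had a log2 fold change of -0.68, Tpm1 of -0.58 and Ldb3 of -0.82, and all 3 fell. The list averaged -0.67, with a camera adjusted p of 6.95e-08, adjusted p = 0.241 with an estimated correlation, and a fry adjusted p of 0.0608. Control 3, the male, had the highest level of this list. Without it the mean was -0.46, with Myh11 at -0.52, Acta2 at -0.48 and Tagln at -0.42. Within lane 7 it was -0.91, with Myh11 at -1.71 and Acta2 at -1.31.

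Matrix-degrading enzymes were partly higher, the call on matrix genes depended on the setting, and fibroblast markers showed little difference. Of 21 proteases and their inhibitors, 8 rose and 1 fell when adjusted over the list alone (0 over all genes). The collagenase gene Mmp13 rose 2.91-fold from 14.9 ± 7.57 to 43.6 ± 14.3 CPM (SD, n = 3 and 5), Mmp14 1.68-fold, and the cathepsin genes Ctss and Ctsc 1.94-fold and 1.65-fold, while Adamts8 fell from 65.2 ± 24.8 to 32.6 ± 7.53 CPM. The protease list averaged 0.44 (camera adjusted p = 7.18e-05, adjusted p = 0.200 with an estimated correlation), and within lane 7 it averaged 0.20, with an adjusted p of 0.111 when lane was a covariate and Mmp13 at 0.95 against 1.54 over all libraries. Extracellular matrix genes averaged 0.22 with 0 of 21 passing adjusted over the list alone and a camera adjusted p of 0.0372, adjusted p = 0.592 with an estimated correlation. Their mean was -0.12 within lane 7, and the call was lost with age as a covariate (adjusted p = 0.190) and without Control 2 (adjusted p = 0.285), caIKK2EC 2 (0.0915), caIKK2EC 3 (0.0820) or caIKK2EC 4 (0.0876). Within that list DESeq2 called Lum (1.97-fold) and Col12a1 (1.86-fold; log2 fold change 0.89, and 0.31 within lane 7) over all genes. The log2 fold change of Lum was 0.98 over all libraries, 1.47 without Control 1 and 0.74 without Control 3, and DESeq2 on females alone did not call it. Eln, the elastin gene, was at 7575 ± 901 CPM in Control and 6579 ± 2442 CPM in caIKK2EC, with a log2 fold change from -0.43 to -0.10 when 1 library was left out. Adventitial fibroblast markers averaged 0.04 over 14 genes with 0 passing in edgeR adjusted over the list alone (camera adjusted p = 0.987), and DESeq2 called Lum, which is in this list too. Genes of endothelial-to-mesenchymal transition averaged 0.09 over 14 genes with 0 passing in edgeR (camera adjusted p = 0.343). DESeq2 called 1 of these over all genes, the transcription factor gene Snai1 (1.75-fold, DESeq2 adjusted p = 0.0320), but not on females alone (adjusted p = 0.146). Calcification genes averaged 0.55, and 2 of 14 rose when adjusted over the list alone, Spp1 and the collagen gene Col10a1 (2.99-fold). That list had a camera adjusted p of 0.00219, adjusted p = 0.200 with an estimated correlation, and within lane 7 it averaged 0.15, with an adjusted p of 0.663 when lane was a covariate.

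The oxidative stress, lipid handling, proliferation, complement and coagulation lists were at higher levels on average. Of 16 oxidative stress genes, 7 rose and 1 fell when adjusted over the list alone (0 over all genes). The phagocyte NADPH oxidase subunit genes Ncf1 and Cybb rose 2.01-fold and 1.94-fold and the haem-degrading enzyme gene Hmox1 1.57-fold. Nqo1 fell to 0.626-fold, a log2 fold change of -0.68 that was -0.40 without Control 3. Neither tool called it over all genes (edgeR adjusted p = 0.217, DESeq2 adjusted p = 0.127). This list averaged 0.41 and 0.36 within lane 7, with a camera adjusted p of 0.00185, adjusted p = 0.188 with an estimated correlation, and a fry adjusted p of 0.0200. Of 20 lipid handling genes, 7 rose and 1 fell when adjusted over the list alone (0 over all genes). Abca1 and Abcg1, which export cholesterol, rose 1.57-fold and 1.54-fold, Ch25h, the cholesterol 25-hydroxylase gene, 2.20-fold, and Fdft1, a cholesterol synthesis gene, fell to 0.715-fold. The lipid handling list averaged 0.22 and also 0.22 within lane 7, with a camera adjusted p of 0.0221, adjusted p = 0.328 with an estimated correlation, and an adjusted p of 0.108 without Control 1. Of 15 proliferation genes, 6 rose and 0 fell when adjusted over the list alone (0 over all genes), among them Tpx2 at 1.71-fold and Mki67 at 1.96-fold, whose log2 fold change of 0.97 was 0.66 without Control 3. The proliferation list averaged 0.70 (camera adjusted p = 1.20e-06, adjusted p = 0.328 with an estimated correlation), 0.59 within lane 7, 0.38 without Control 3 and 1.08 without Control 1. Complement genes averaged 0.34 and 0.61 within lane 7, and 3 of 18 rose when adjusted over the list alone, the anaphylatoxin receptor genes C3ar1 (1.85-fold) and C5ar1 (2.08-fold) and the complement inhibitor gene Cd55 (3.40-fold). The complement list had a camera adjusted p of 0.00196, adjusted p = 0.328 with an estimated correlation. Coagulation genes averaged 0.25 and 0.22 within lane 7, with 0 of 14 passing in edgeR adjusted over the list alone and 1, Vwf, called by DESeq2 over all genes. The camera adjusted p of this list was 0.0221, adjusted p = 0.200 with an estimated correlation. That call was lost without Control 3 (0.13, adjusted p = 0.109) and with sex (0.13, adjusted p = 0.114) or lane (adjusted p = 0.133) as a covariate.

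Markers of tissues around the aorta varied between single libraries. Brown adipocyte genes averaged -0.93 and white adipocyte genes -0.39, with 0 of 9 and 0 of 12 passing adjusted over the list alone. Their camera adjusted p-values were 0.0425 and 0.0224, adjusted p = 0.611 and adjusted p = 0.592 with an estimated correlation. Within lane 7 the means were 1.00 and 0.69, and without caIKK2EC 2 they were -0.40 (adjusted p = 0.231) and -0.21 (adjusted p = 0.182). Both calls were also lost without Control 2 (adjusted p = 0.0546 and adjusted p = 0.0853), without caIKK2EC 4 (adjusted p = 0.0575 and adjusted p = 0.0602) and with age as a covariate (adjusted p = 0.306 and adjusted p = 0.223). The brown adipocyte call was lost as well without Control 1 (adjusted p = 0.116) and with a stricter filter (adjusted p = 0.0566). Without caIKK2EC 1 the means were -1.40 and -0.65. With lane as a covariate both lists were called higher (adjusted p = 0.0144 and adjusted p = 0.00139). Ucp1, the uncoupling protein of brown fat, was at 623, 782 and 844 CPM in Control 1 to 3 and at 1512, 37.5, 382, 247 and 404 CPM in caIKK2EC 1 to 5. Cardiomyocyte genes averaged -0.48 (0 of 11 passing, camera adjusted p = 0.158) and turned with single libraries. They averaged 1.10 without Control 1 (adjusted p = 0.340) and 2.19 with lane as a covariate (adjusted p = 0.0597). In lane 7 alone they were called higher (2.16, adjusted p = 0.0350). They were called lower without Control 2 (-1.17, adjusted p = 0.0156), Control 3 (-1.34, adjusted p = 0.00428) or caIKK2EC 1 (-1.14, adjusted p = 0.0102). With sex as a covariate they were called lower too (-1.33, adjusted p = 0.00604), and with age they averaged 0.13. The heart myosin gene Myh6 was at 902 CPM in Control 1 and 480 CPM in caIKK2EC 1 and at 5.05 to 23.02 CPM in the other 6 libraries. Skeletal muscle genes averaged -0.76 over 6 genes with an adjusted p of 0.260, and 0.05 without Control 1, and Schwann cell genes -0.04 over 9 genes with an adjusted p of 0.983. Immediate early genes, which respond to handling, averaged -0.06 over 13 genes with a median of 0.03 and an adjusted p of 0.816, and -0.73 with lane as a covariate (adjusted p = 0.000435). In these 3 lists 0 genes passed adjusted over the list alone. Of the erythroid list only 1 gene was measured, and that list was not tested.

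Among the genes that DESeq2 called over all genes, the 10 with the largest increase and no overlap between groups were Serpina3f, Robo2, Gal, Abca13, Serpina3i, Cyp4f18, Serpina3g, Grem1, Cd55 and Gpr171. Robo2, which encodes a receptor for the guidance protein Slit (chromosome 16, 73891839 to 74411825, minus strand), was at 0.729 ± 0.120 CPM (SD, n = 3) in Control and 4.24 ± 1.03 CPM (SD, n = 5) in caIKK2EC, with a DESeq2 adjusted p of 4.20e-10 and an edgeR adjusted p of 0.107. Cd55 (chromosome 1, 130439027 to 130462744, minus strand) was at 23.3 ± 13.5 and 79.3 ± 10.2 CPM with a DESeq2 adjusted p of 0.000166. Grem1, an antagonist of bone morphogenetic proteins, was 3.73-fold higher (DESeq2 adjusted p = 0.000321), and Gal, the neuropeptide galanin, was at 0.588 ± 0.164 and 3.32 ± 2.33 CPM. Serpina3f, Serpina3g and Serpina3i are neighbouring copies of a serine protease inhibitor gene and can share reads, so the level of each alone is uncertain. Those with the largest decrease included Ihh, Casq1, Klk10, Slc22a2, Col19a1, Rab17, Gja6, Ky and Mylk4. Ihh, which encodes the signalling protein Indian hedgehog, was at 5.80 ± 2.58 CPM in Control and 1.36 ± 0.674 CPM in caIKK2EC (DESeq2 adjusted p = 0.000481). The kinase gene Mylk4 was at 264 ± 135 and 97.1 ± 33.6 CPM (DESeq2 adjusted p = 0.00177). Without Control 3 the log2 fold change of Casq1 was -1.23 against -1.86 and that of Slc22a2 -1.17 against -1.79. Likewise Gja6 was at -1.04 against -1.58, Ky at -0.99 against -1.51 and Mylk4 at -0.95 against -1.44, whereas Cyp4f18 was at 3.05 against 2.00. Serpina3f ranged from 2.33 to 3.39 when 1 library was left out, against 2.80. Neither set passed edgeR's test over all genes.

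**Figure D2:**
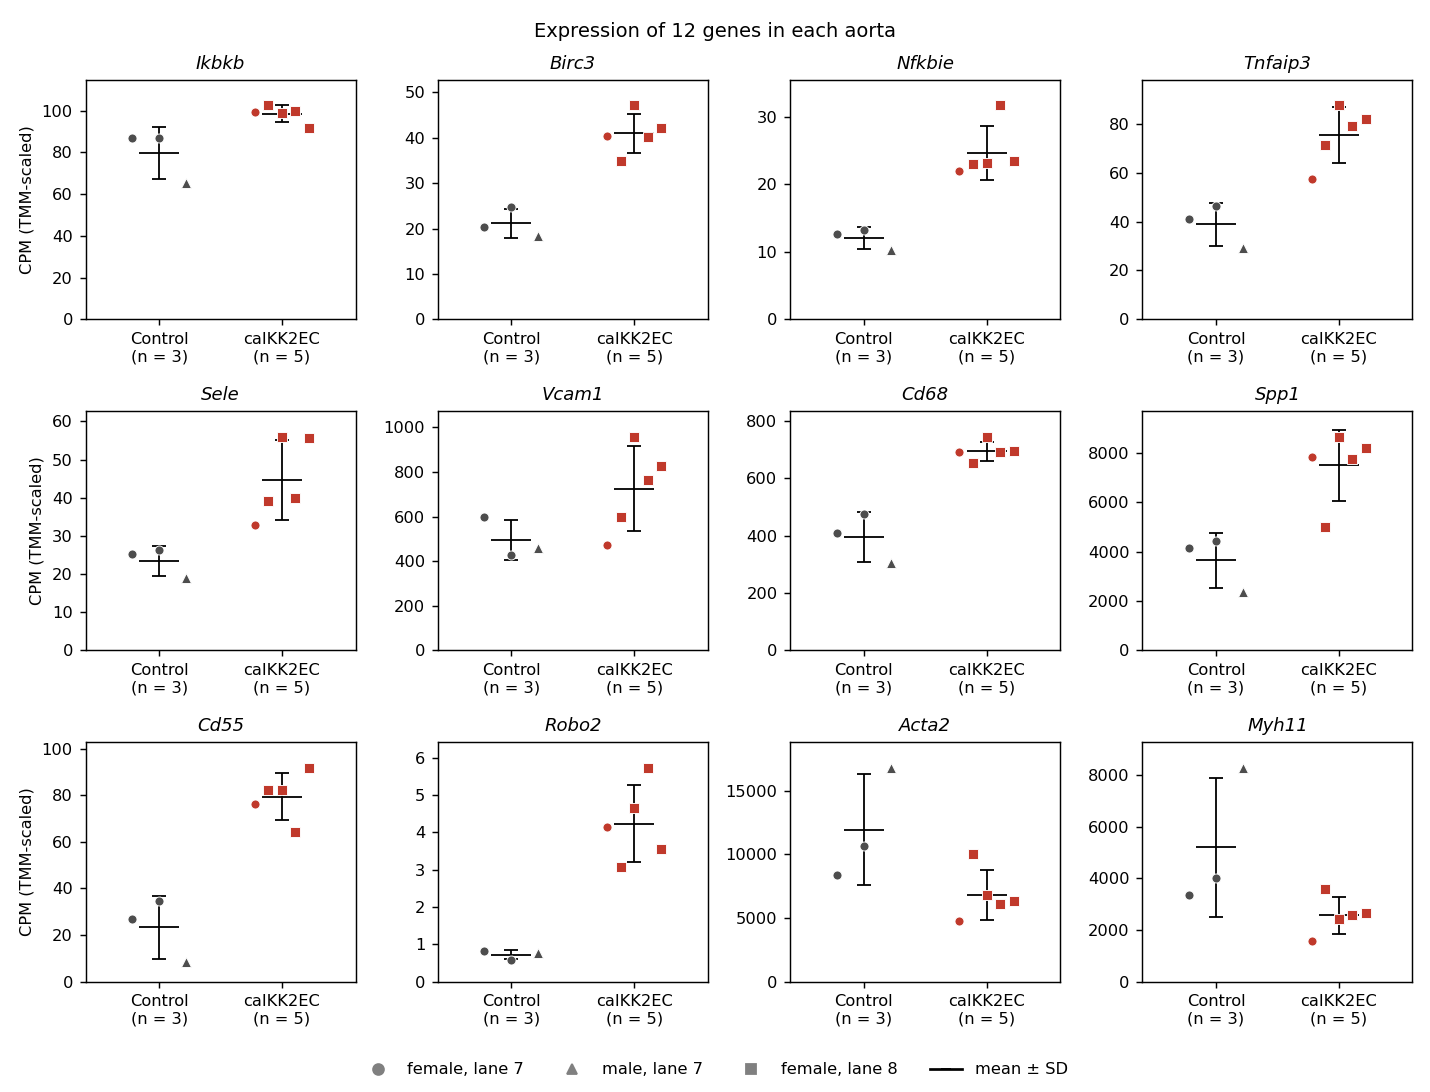
Levels of 12 genes in CPM, scaled by TMM factors (vertical axes from 0), in the 3 Control and 5 caIKK2EC libraries; circles are females and triangles the male in lane 7, squares are females in lane 8, and bars give the mean ± SD. Birc3, Nfkbie, Tnfaip3, Sele, Cd68, Spp1, Cd55, Robo2 and Ikbkb were higher in every caIKK2EC library than in every Control. None of these passed edgeR's test over all genes, and DESeq2 called all but Ikbkb. Vcam1 overlapped, and Acta2 and Myh11 were highest in the male Control.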

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

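Tests with lane, with library weights, without 2 libraries at once, with DESeq2 on fewer libraries, without robust fitting and with bias-adjusted deviances were chosen only after the result was seen; the others were planned. The edgeR count of 0 genes (2515 at an unadjusted p under 0.05) stayed at 0 with DESeq2 size factors, upper quartile scaling, no filter, a stricter filter, sex, lane 7 alone or lane as a covariate, limma-voom, a test against 1.5-fold, no robust fitting, bias-adjusted deviances, and thresholds of 0.01 and 0.1. It became 661 with age as a covariate (407 higher, 254 lower), 655 with library weights in limma-voom, 320 without Control 3 and caIKK2EC 2, 869 with DESeq2, 389 with DESeq2 on females and 1782 with DESeq2 without caIKK2EC 2. Leaving out 1 library gave 0 to 359 genes, with 359 without caIKK2EC 2 and 0 in each of the other 7 cases. In all, over 91 named genes, 1986 of 2363 values under an alternative kept direction and side of the threshold, 369 passed it where edgeR had not and 8 reversed. Over 36 lists 597 of 756 did, 96 lost and 20 gained a call and 43 reversed. The cause of these changes was not tested, except that fewer libraries were fitted where libraries were left out. At this depth genes under 1 CPM, such as Robo2 and Gal in Control, rest on few counts, so their folds can be imprecise. When 1 library was left out, the log2 fold change of Gal ranged from 1.97 to 2.76 and that of Robo2 from 2.42 to 2.64.

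The replicate numbers of the labels do not pair the samples: the deviations of same-numbered libraries correlated by 0.335, 0.099 and 0.097 across genes, and Control 3 correlated best with caIKK2EC 4 (0.180). With the replicate number as a block (replicate block, 6 libraries) edgeR called 0 genes, and camera called 19 lists higher and 4 lower; the block turned the Schwann cell list to 0.00 and Myh6 to 0.56. The endothelial identity list gained a call (0.28, adjusted p = 0.0165), and the plasma cell (adjusted p = 0.0630), matrix (0.154) and lipid handling (0.0523) lists lost theirs.

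Of 36 lists, 21 were higher and 4 lower. With an estimated correlation 0 and 0 were called, so the NF-κB (0.53), macrophage (0.77) and smooth muscle (-0.67) lists kept their values and lost their calls. With fry 8 and 0 were called, and the smooth muscle list (-0.67) lost its call. The number lower was 2 with the stricter filter and 2 with age. Leaving out 1 library gave 18 to 22 lists higher and 2 to 6 lower, with 2 lower without Control 1, caIKK2EC 2 or caIKK2EC 4.

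The following mean log2 fold changes of lists changed sign. With the stricter filter the B cell list was 0.38, and with no filter the Schwann cell list 0.08. With sex as a covariate neutrophil genes were -0.20, mast cell genes -0.03, endothelial identity genes -0.04 and fibroblast genes -0.08. With age the cardiomyocyte list was 0.13. With lane as a covariate the lists were at -0.12 for matrix, -0.08 for endothelial-to-mesenchymal transition, 0.69 for white and 1.00 for brown adipocytes, 2.19 for cardiomyocytes, 0.91 for skeletal muscle and 0.08 for Schwann cells. In lane 7 alone they were at -0.12, -0.08, 0.69, 1.06, 2.16, 0.63 and 0.08. Without Control 3 and caIKK2EC 2 neutrophil genes were -0.30, mast cell genes -0.01, lymphoid stroma -0.19 and fibroblast genes -0.12, and with limma-voom neutrophil genes were -0.05.

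When 1 library was left out, lists ranged from -0.62 to 0.27 for B cells, -0.23 to 0.24 for neutrophils, -0.03 to 0.32 for mast cells, -0.14 to 0.51 for lymphoid stroma, -0.04 to 0.39 for endothelial identity, -0.07 to 0.17 for fibroblasts, -1.34 to 1.10 for cardiomyocytes, -1.22 to 0.05 for skeletal muscle, -0.09 to 0.07 for Schwann cells and -0.19 to 0.12 for immediate early genes. The NF-κB list ranged from 0.43 to 0.62, the macrophage list from 0.59 to 0.93 and the smooth muscle list from -0.81 to -0.46. Of the named genes, Vcam1 was -0.07 with lane as a covariate and -0.06 in lane 7 alone, Ucp1 1.01 in both, and Myh6 0.66 in both and -4.46 to 4.23 when 1 library was left out.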

Other observations

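The tests on macrophage, smooth muscle and NF-κB lists and the counts over splits of the libraries were all chosen or specified only after the results they address were seen. Serpina3n, which encodes a secreted inhibitor of serine proteases induced in inflammation, was at 247 ± 42.6 CPM (SD, n = 3) in Control and 602 ± 150 CPM (SD, n = 5) in caIKK2EC aortas (2.43-fold, DESeq2 adjusted p = 5.49e-06, edgeR adjusted p = 0.107). It lies in a cluster of similar gene copies that can share reads, so its level alone is uncertain. On a principal component analysis of all libraries, Control 3 lay at 75.8 on the first component (32.4% of the variance) and the other 7 between -35.0 and 11.1.

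Over all 56 splits of the 8 libraries into 3 and 5, the real split was the only 1 with as many as 2515 genes at an unadjusted p under 0.05 (highest other 2285), as many as 869 DESeq2 calls (highest other 517) and as many as 25 lists called by camera (highest other 24). Each of these 3 counts thus ranked first (1 of 56 splits, the smallest share possible). They come from the same values and were chosen after the results were seen. For the counts of genes the rank argues against chance without excluding it. For the lists the margin was 1 list, and other splits gave 24, 22 and 21, so for that count chance stays open. The rank also does not set genotype apart from lane, which the real split follows except for caIKK2EC 1. For the edgeR count of 0 genes at an adjusted p under 0.05 the splits decide nothing, since all 56 must give at least 0 (highest other 1). The next highest count of genes, 2285 at an unadjusted p and 517 in DESeq2, came from the split of caIKK2EC 3, 4 and 5 against the rest. These 3 shared lane 8, but so did caIKK2EC 2 on the other side. A split that crosses the lanes, Control 2, Control 3 and caIKK2EC 2 against the rest, gave almost as many (2218 and 498).

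Macrophage markers were higher and smooth muscle genes lower together, and the male Control alone was argued against. Among females the macrophage list still differed by 0.59 (SE 0.14) and the smooth muscle list by -0.46 (SE 0.13). That was judged by a limit of 2 standard errors without an exact test. Control 1 and Control 2 were the only Controls left, so these standard errors are themselves uncertain. A smaller share of smooth muscle RNA that raises all other cell types alike was argued against by the macrophage list, which rose above the mean of the endothelial, fibroblast and Schwann cell lists by 0.70 (SE 0.09, exact permutation p = 0.0357), and of whose 21 genes 0 are in another list. With lane as a covariate camera still called both lists (0.89 for macrophage markers, -0.91 for smooth muscle genes), but that genotype difference rests on caIKK2EC 1, the 1 caIKK2EC library on the Controls' lane, so lane and genotype cannot be told apart. Among abundant macrophage genes, Cd68 was at 395 ± 85.7 CPM in Control and 694 ± 33.1 CPM in caIKK2EC, while Lyz2, at 3000 ± 2136 and 5733 ± 1116 CPM, passed in neither tool (edgeR adjusted p = 0.403, DESeq2 adjusted p = 0.241) and its log2 fold change of 0.93 was 0.44 without Control 3. More macrophages and more transcript per macrophage both stay open, and no test here separates them.

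The NF-κB list was higher by 0.53. The male Control alone was argued against by the difference of 0.43 (SE 0.05) among females. That was judged by a limit of 2 standard errors, with Control 1 and Control 2 as the only Controls and no exact test. More macrophage RNA alone stays open as a candidate explanation: 3 adhesion genes of inflamed endothelium (Sele, Selp and Ackr1), a set chosen after the gene values were seen, lay above the endothelial identity list by 0.47 (SE 0.23) without reaching significance (exact permutation p = 0.107), with Sele at 0.69 (SE 0.20, p = 0.0714), Ackr1 at 0.59 (SE 0.53, p = 0.286) and Selp at 0.14 (SE 0.15, p = 0.464). The criterion of that exact p was set after the value was seen, and a limit of 2 standard errors would have argued against it. Against the macrophage list itself, the NF-κB list rose by less (-0.23, SE 0.13, exact permutation p = 0.143), without reaching significance. No gene of the NF-κB list is in the macrophage list, though macrophages express many of its genes, and lane cannot be told apart from genotype here either, since the 0.44 with lane as a covariate rests on the same library.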
